A study of Mus musculus with 18 samples.

How the data were processed

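Total RNA of Kupffer cells, the resident macrophages of the liver, was sequenced in 18 libraries from wild-type C57BL/6J mice, in 6 groups of 3. The cells were obtained by collagenase perfusion, density gradient and adherence, per the labels' protocols. Reads were aligned with HISAT2 to the GRCm38 mouse genome, per the submitters' processing notes. The program that counted reads, its annotation and all versions are not given in the sources used here.

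The authors deposited 3 tables. The time-course tables, one for 0 h and 3 h and one for 6 h and 12 h, hold expected counts (estimated counts that need not be whole) and FPKM per gene with an Entrez gene identifier, per the file headers and their values. In these, 35.3% to 36.2% of the values were not whole. The table of the antibody groups holds whole-number counts per gene with an Ensembl identifier, per the file headers. The TPM columns that the authors deposited beside the FPKM were not used here. The FPKM served as an alternative only. Columns were matched to samples by name, and no unmatched column was used.

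Among the symbols for the antibody groups, 27 had turned into dates, and all 27 were restored from their Ensembl identifiers through the GENCODE reference table, which held 22022 of the 24781 identifiers. Another 19 symbols were shared by more than 1 identifier. The identifier with the largest total count kept the symbol. This rule was set after Aldoa was found missing from a first run, so that genes of the fixed panel and lists could be found. Positions are those of the GRCm38 annotation.

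Expected counts were rounded to whole numbers. Each comparison was fitted within its own table, because the tables were made separately: 3 h against 0 h, 12 h against 6 h, and anti-CD41 against IgG. Genes were kept by edgeR's filterByExpr with a minimum count of 10, scaled by TMM and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Levels are CPM (counts scaled to a library total of 1e6) on the TMM scale, computed from the deposited counts, except across the time course, where they are plain CPM. A gene called higher or lower passed the threshold. The smallest p of an exact permutation test of 3 against 3 samples is 0.1, so none was used.

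The comparisons, the tests, the 29 gene lists, the panel of 16 genes and the rule for named genes were fixed before the data were examined. The plan named edgeR for whole-number counts and limma where only FPKM was held. It did not cover expected counts with FPKM beside them, so the rounding of these counts for edgeR was not fixed by it. The lists hold 549 genes, of which 13 stand in more than 1 list. Lists with at least 5 tested genes were tested with limma camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, then again with an estimated correlation. The estimated setting takes its degrees of freedom from the samples and not from the genes, so it is the weaker test with 3 libraries per group. Limma's fry, which tests a list by itself and not against the other genes, was run beside camera. Its p is given for 12 h against 6 h only. The text names, per comparison, up to 6 called genes with the largest rise and up to 6 with the largest fall among genes whose groups did not overlap and whose higher group mean was at least 5 CPM, leaving out predicted genes and pseudogenes by name, then the panel, then up to 4 members of each list with the smallest p. Other members are named where a list had few called genes, and these were chosen after their values were seen.

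The alternatives were each library left out in turn, DESeq2 size factors within edgeR, DESeq2 1.42.0, no expression filter, the replicate number as a block, camera with an estimated correlation and, in the time-course tables, limma on log2(FPKM + 1) over genes with at least 1 FPKM in 3 libraries. The alternatives voom with library weights and the glycolysis list without Gapdh were added after the data were seen.

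Total counts were 18644317 to 19954179 per library at 0 h and 3 h, 19024955 to 20583052 at 6 h and 12 h, and 28017439 to 38382509 in the antibody groups. The common biological coefficient of variation was 0.201, 0.371 and 0.267 in the same order. No library pair differed by as little as sampling noise: the lowest chi-square per degree of freedom over genes with a summed count of at least 20 was 15.8. The tests were tried on simulated counts with known changes in few genes. For 3 h against 0 h, 99 tested genes were changed 2-fold and 98 were changed 4-fold. In the real data of that comparison 42.1% of genes were called, so the share recovered there may differ. For 3 h against 0 h (14047 genes) the tests recovered 41.4% of 2-fold and 95.9% of 4-fold changes, with 12 false calls among 147. For 12 h against 6 h (13841 genes) they recovered 0% and 33.7%, with 0 false calls among 33. For anti-CD41 against IgG (14611 genes) they recovered 42.4% and 90.7%, with 12 false calls among 142.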

Results

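RNA was sequenced from Kupffer cells of mice given acetaminophen, a drug whose overdose injures hepatocytes. A time course had 3 libraries each at 0 h, 3 h, 6 h and 12 h. A further 3 libraries came from mice given acetaminophen with an antibody to CD41, the platelet integrin subunit encoded by Itga2b, and 3 from mice given acetaminophen with IgG. Antibodies to CD41 are used to deplete platelets. The labels give no time for the antibody groups. The columns of the 0 h libraries are named for PBS, whereas their treatment label also names acetaminophen, so this group is described by its time only. The series title concerns aldolase passed from platelets to Kupffer cells and the metabolism of these cells, which makes aldolase and glycolysis the first genes of interest. Total counts were 18644317 to 19954179 per library at 0 h and 3 h, 19024955 to 20583052 at 6 h and 12 h, and 28017439 to 38382509 in the antibody groups. The labels do not say that replicates came from separate animals, so the p-values measure the spread between these samples.

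The first comparison asked how the cells differed 3 h after acetaminophen from 0 h. Several cytokine and chemokine genes rose, and hepatocyte markers and genes of mitochondrial metabolism fell. Slc10a6 (gene identifier 75750), which encodes a transporter of sulfated steroids, rose from 0.534 ± 0.283 to 30.1 ± 12.9 CPM (SD, n = 3 each). Igfbp1, which encodes a binding protein of insulin-like growth factors, rose by 5.71 on the log2 scale, the neutrophil chemokine gene Cxcl3 by 4.99, the granulocyte colony-stimulating factor gene Csf3 by 4.72, Tgfb3 by 4.61 and Rnd1 by 3.88. The largest falls under the naming rule were in genes of hepatocyte function or identity: Adh4 fell by 5.68, the transcription factor gene Onecut1 by 5.66, Anks4b by 5.53, the steroid dehydrogenase gene Hsd3b5 by 5.40 and Rgn from 42.5 ± 18.7 to 1.31 ± 0.742 CPM. The major urinary protein gene Mup9 fell by 6.24 but has near-identical copies and is uncertain. It had no reads in 3 h replicates 1 and 3, so that its fitted value without replicate 2, -13.68, depends on the prior count and is no measured fold.

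By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5967 of 14161 tested genes (42.1%) were called at 3 h, 2703 higher and 3264 lower, of which 952 and 1340 changed at least 2-fold. The groups did not overlap in 55.6% of genes, against 10% by chance. With the deposited FPKM, limma called 1783 genes higher and 3381 lower, a higher share of 34.5% against 45.3%, and the median of all genes lay at -0.11 rather than -0.01 on the log2 scale. The FPKM changes are on the log2(FPKM + 1) scale, which understates those of low genes. On it Slc10a6 rose by 3.66 and Igfbp1 by 3.57, and the values of Onecut1, Anks4b and Hsd3b5 were -2.91, -2.87 and -2.13, with each of the 5 called. The counts were 1599 higher and 2116 lower without 0 h replicate 2, and 1657 and 1855 without 3 h replicate 3.

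Aldoa (gene identifier 11674; GRCm38 chromosome 7, 126795234 to 126800994) encodes aldolase A, the glycolytic aldolase of most cells. Its level was 468 ± 41.5 CPM at 0 h and 439 ± 20.2 CPM at 3 h (SD, n = 3 each), a log2 difference of -0.09 ± 0.12 (SE) that was not called (edgeR adjusted p = 0.554). Of the 21 glycolysis genes, 4 rose, 7 fell and 10 were not called. Adjusted over the list alone, 6 rose and 7 fell. Pfkfb3, which makes the activator of phosphofructokinase, rose from 89.6 ± 2.83 to 269 ± 95.8 CPM, and the glucose transporter gene Slc2a3 rose by 1.45 on the log2 scale, with smaller rises of Gpi1 (0.49) and Hk1 (0.26). Eno1 fell by 1.00, Pgk1 by 0.91, Pgam1 by 0.83 and Ldha by 0.77, whereas the pyruvate kinase gene Pkm was 649 ± 125 and 698 ± 49.5 CPM and was not called (edgeR adjusted p = 0.634). As a whole the list was not called (limma camera adjusted p = 0.831). Its median log2 change was 0.06, its mean -0.03 and its test direction down, and the median was -0.02 with the deposited FPKM. In the pentose phosphate pathway 1 of 7 genes rose (Taldo1, 0.44) and 3 fell (Rpe, Rpia and G6pdx), the same counts as adjusted over the list alone, and the list was not called (camera adjusted p = 0.218). Without 3 h replicate 3 Rpia was not called (edgeR adjusted p = 0.0585). Taldo1 was not called without 0 h replicate 2 (0.136), 0 h replicate 3 (0.12), 3 h replicate 2 (0.114) or 3 h replicate 3 (0.129), nor with no expression filter (0.0529) or with FPKM (0.0602). G6pdx was not called without any one of the 6 libraries (0.0622 to 0.171), with DESeq2 size factors within edgeR (0.0633) or with no expression filter (0.0703).

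Genes of mitochondrial metabolism fell together at 3 h. In the tricarboxylic acid cycle 15 of 20 genes fell and none rose, among them Fh1 (fumarate hydratase) by 1.53 and Idh3b by 0.89. In oxidative phosphorylation 26 of 28 genes fell and none rose, with Uqcrq down from 81.4 ± 25.4 to 27.6 ± 3.88 CPM and Cycs (cytochrome c) from 130 ± 29.6 to 53.5 ± 8.13 CPM. In fatty acid oxidation 13 of 18 genes fell, among them Eci1 by 2.05 and Cpt2 by 1.82, while Cpt1a, the carnitine palmitoyltransferase of the outer membrane, rose by 0.72. Adjusted over the list alone the falls numbered 17, 27 and 13. The list medians were -0.63, -0.76 and -1.36 (camera adjusted p = 1.9e-04, 1.1e-06 and 0.00548), and for each list adjusted p = 0.723 with an estimated correlation. Beside these genes, hepatocyte markers fell: 11 of 22 fell and none rose, 17 fell adjusted over the list alone, and their median was -1.10 (camera adjusted p = 1.1e-04, adjusted p = 0.723 with an estimated correlation). The hepatocyte P450 gene Cyp2e1 fell from 213 ± 50.9 to 47.8 ± 8.83 CPM. In mean log2(CPM + 1), hepatocyte markers were 7.83, 8.62 and 8.55 in 0 h replicates 1, 2 and 3. Oxidative phosphorylation was 5.92, 6.51 and 6.44 in these libraries, likewise lowest in replicate 1. At 3 h hepatocyte markers were lowest in replicate 1 (6.18), but oxidative phosphorylation in replicate 3 (5.39). Whether the mitochondrial genes fell within Kupffer cells or through the mix of cells was not tested. Heat shock genes fell as well, 10 of 13 over all genes and 11 adjusted over the list alone, with Hsph1 down by 2.52 and the mitochondrial chaperone gene Hspd1 by 1.85 (median -1.01; camera adjusted p = 0.00254, adjusted p = 0.723 with an estimated correlation).

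Cytokine genes moved in both directions at 3 h. Of 23 inflammatory cytokine and chemokine genes, 6 rose (Il1b, Il6, Csf3, Cxcl1, Cxcl2 and Cxcl3), 16 were not called and Ccl2, which attracts monocytes, fell by 0.75; the counts were the same adjusted over the list alone. Il6 rose from 36.5 ± 14.9 to 198 ± 83.0 CPM and the anti-inflammatory cytokine gene Il10 from 25.7 ± 11.1 to 206 ± 118 CPM, whereas Tnf was 278 ± 131 and 254 ± 66.3 CPM and was not called. Il1b was called at 709 ± 321 and 1736 ± 489 CPM (edgeR adjusted p = 0.025), but not without 0 h replicate 2 (0.089), 0 h replicate 3 (0.0629), 3 h replicate 2 (0.0543) or 3 h replicate 3 (0.0865). The call of Ccl2 was lost without 0 h replicate 1 (0.0602), 0 h replicate 2 (0.0613), 3 h replicate 1 (0.0746) or 3 h replicate 2 (0.0793). The list median was 0.49 (camera adjusted p = 0.0494, adjusted p = 0.759 with an estimated correlation). That call was lost without 0 h replicate 2 (camera adjusted p = 0.0689), 0 h replicate 3 (0.135), 3 h replicate 2 (0.176) or 3 h replicate 3, where the median was 0.003 (0.404), as well as with DESeq2 size factors within edgeR (0.052) and with no expression filter (0.106). The median was 0.76 without 0 h replicate 1 and 0.83 without 3 h replicate 1.

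Among 19 genes of NF-kB feedback and activation 5 rose (4 adjusted over the list alone) and none fell. Socs3, an inhibitor of cytokine signalling, rose from 384 ± 45.7 to 2049 ± 499 CPM, Tnfaip3 by 1.92, Birc3 by 1.63, Zc3h12a by 1.15 and Ier3 by 0.99. The median was 0.56 (camera adjusted p = 0.0138, adjusted p = 0.723 with an estimated correlation). Without 0 h replicate 3 it was 0.34 (camera adjusted p = 0.101) and without 3 h replicate 2 it was 0.52 (camera adjusted p = 0.0607), while it was 0.90 without 0 h replicate 1, 0.85 without 3 h replicate 1 and 0.36 without 3 h replicate 3. Interferon-stimulated genes fell: 11 of 22 fell over all genes and adjusted over the list alone, among them Ifi44 by 1.22 and Oas3 by 1.19, and Oasl1 rose by 0.96 (median -0.50; camera adjusted p = 0.00733, adjusted p = 0.723 with an estimated correlation). Of 19 repair and anti-inflammatory macrophage genes 4 rose and 4 fell over all genes and adjusted over the list alone. The scavenger receptor gene Cd163 rose from 441 ± 91.9 to 1467 ± 387 CPM, Il4ra by 1.89 and Mrc1 by 1.11, while Fn1 fell by 2.93, Lgals3 by 0.78, Tgfb1 by 0.61 and Arg1 by 2.65. Arg1 was not called without 0 h replicate 2 (edgeR adjusted p = 0.0748), 0 h replicate 3 (0.0507) or 3 h replicate 3 (0.0776). The list was not called (camera adjusted p = 0.832), and its median of -0.03 and mean of -0.06 lay below 0 while its test direction was up.

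NRF2 targets, which answer oxidative stress, included 7 of 17 genes that rose and 2 that fell, over all genes and adjusted over the list alone. Srxn1 (sulfiredoxin) rose from 55.4 ± 6.02 to 207 ± 31.8 CPM and Txnrd1 (thioredoxin reductase) by 1.04, while Me1 fell by 2.60 and G6pdx by 0.38. Among 17 hypoxia targets outside glycolysis 8 rose and 1 fell (P4ha1), again the same adjusted over the list alone, with Mxi1 up by 1.85 and Ndrg1 by 1.25. Among 21 phagocytosis and efferocytosis receptor genes 7 rose and 2 fell (Msr1 and Fcgr1), likewise adjusted over the list alone, with Fcgr3 up by 1.31 and Timd4, which binds phosphatidylserine, by 0.91. Of 24 cell cycle genes Mki67 rose from 39.0 ± 4.96 to 219 ± 115 CPM and Ccnb2 was called, and 22 were not called (1 called adjusted over the list alone). The medians of these lists were 0.31, 0.27, 0.28 and 0.18 (camera adjusted p = 0.0494 for each, adjusted p = 0.723 with an estimated correlation). Each call was lost without single libraries: NRF2 without 0 h replicate 3 (0.0723), 3 h replicate 2 (0.14) or 3 h replicate 3 (0.0883); hypoxia without 0 h replicate 1 (0.0766), 0 h replicate 3 (0.0734), 3 h replicate 1 (0.0713) or 3 h replicate 2 (0.0667). The receptor list lost its call without 0 h replicate 1 (0.0643), 0 h replicate 2 (0.0685), 3 h replicate 1 (0.0636) or 3 h replicate 3 (0.051). The cell cycle list lost it without 0 h replicate 1 (0.139), 0 h replicate 2 (0.0689) or 3 h replicate 1 (0.053). Calls were also lost with DESeq2 size factors within edgeR (NRF2, 0.0519; hypoxia, 0.052), with no expression filter (NRF2, 0.0548; hypoxia, 0.0591; receptors and cell cycle, 0.0523), with voom with library weights (hypoxia, 0.0668; cell cycle, 0.0753) and with DESeq2 (cell cycle, 0.105). With FPKM the medians were 0.21 (NRF2) and 0.05 (cell cycle). They moved to 0.50 (NRF2), 0.42 (hypoxia), 0.56 (receptors) and 0.30 (cell cycle) without 0 h replicate 3, and to 0.42 (hypoxia) without 3 h replicate 2. Among single genes, Fcgr1 was not called without 3 h replicate 2 (edgeR adjusted p = 0.0583) or 3 h replicate 3 (0.0714), G6pdx not without any one library (0.0622 to 0.171), and Ccnb2 not without any library other than 3 h replicate 1 (0.0516 to 0.0855).

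Markers of other cell types also differed at 3 h. Monocyte-derived macrophage markers fell, 10 of 18 over all genes and 11 adjusted over the list alone, with Cx3cr1 down from 93.8 ± 52.0 to 3.09 ± 0.285 CPM (median -1.78; camera adjusted p = 0.00276). Neutrophil markers rose, 9 of 20 over all genes and 12 adjusted over the list alone, with Il1r2 up from 35.5 ± 19.4 to 385 ± 104 CPM, while Prtn3 fell by 2.88, with a value of -1.68 with FPKM (list median 1.43; camera adjusted p = 0.00376). Platelet and megakaryocyte transcripts rose, 10 of 16 over all genes and 11 adjusted over the list alone. Among them Itgb3 rose from 41.8 ± 6.40 to 127 ± 16.6 CPM and the platelet chemokine gene Ppbp from 0.715 ± 0.108 to 2.40 ± 0.306 CPM (by 0.93 on the log2 scale with FPKM), while Gng11 fell by 0.94 (median 0.96, 0.63 with FPKM; camera adjusted p = 0.0138). For each of these lists adjusted p = 0.723 with an estimated correlation. Of the 20 Kupffer cell markers 8 rose, among them Slc16a9 by 1.95, and 3 fell, Paqr9 by 1.98, Kcna2 by 1.60 and Nr1h3 by 1.57; 8 rose and 4 fell adjusted over the list alone, and the list was not called (median 0.44; camera adjusted p = 0.25). The Kupffer marker Clec4f was 1568 ± 391 and 2252 ± 310 CPM and was not called (edgeR adjusted p = 0.0939). The sinusoidal endothelial list was not called (median 0.21; camera adjusted p = 0.202), with 3 genes higher (Stab2, Oit3 and Ptprb) and 3 lower (Gpr182, Egfl7 and Vwf), as adjusted over the list alone. It was called higher without 0 h replicate 2 (median 0.31, camera adjusted p = 0.0263). Gpr182 was not called without 3 h replicate 3 (edgeR adjusted p = 0.0618), Stab2 not without 0 h replicate 3 (0.0576) or 3 h replicate 3 (0.0708), and Egfl7 not without 0 h replicate 2 (0.0701), 0 h replicate 3 (0.0553), 3 h replicate 1 (0.0622) or 3 h replicate 2 (0.0581).

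The other lists at 3 h had few called genes or an uncertain call. Unfolded protein response genes were mixed, with Chac1 and Ppp1r15a higher and 7 of 16 lower, among them the chaperone cofactor gene Sdf2l1 by 2.24 (3 and 7 adjusted over the list alone; median -0.24; camera adjusted p = 0.156). The list was called lower with DESeq2 (camera adjusted p = 0.00212) and without 0 h replicate 3 (median -0.38). Of 23 immediate early genes 4 rose, among them Fosl1 by 2.50 (by 1.47 with FPKM), and 2 fell (3 and 2 adjusted over the list alone; median 0.29; camera adjusted p = 0.156), and the list was called higher without 0 h replicate 1 (0.37, camera adjusted p = 0.0455). Cholangiocyte markers had 3 of 9 genes lower over all genes and over the list alone, among them Sox9 and Tm4sf4 (median -1.13; camera adjusted p = 0.0494, adjusted p = 0.723 with an estimated correlation). This call was lost without 0 h replicate 1 (median -0.34, camera adjusted p = 0.268), 3 h replicate 2 (0.0823) or 3 h replicate 3 (0.0768), and with DESeq2 size factors within edgeR (0.0519), voom (median -0.54, 0.146) or FPKM (0.087). Tm4sf4 was not called without 0 h replicate 2 (0.0508), 3 h replicate 2 (0.06) or 3 h replicate 3 (0.0511). Not called were stellate markers (median 0.09; camera adjusted p = 0.832; 1 of 17 genes lower, 0 over the list alone), T and NK cell markers (0.16; 0.512; 3 of 19 higher and 1 lower), B cell markers (-0.25; 0.34; 1 of 13 higher and 3 lower), dendritic cell markers (-0.40; 0.149; 7 of 16 lower) and erythroid genes (0.61; 0.3; 1 of 7 lower), the last 4 with the same counts over the list alone.

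**Figure D1:**
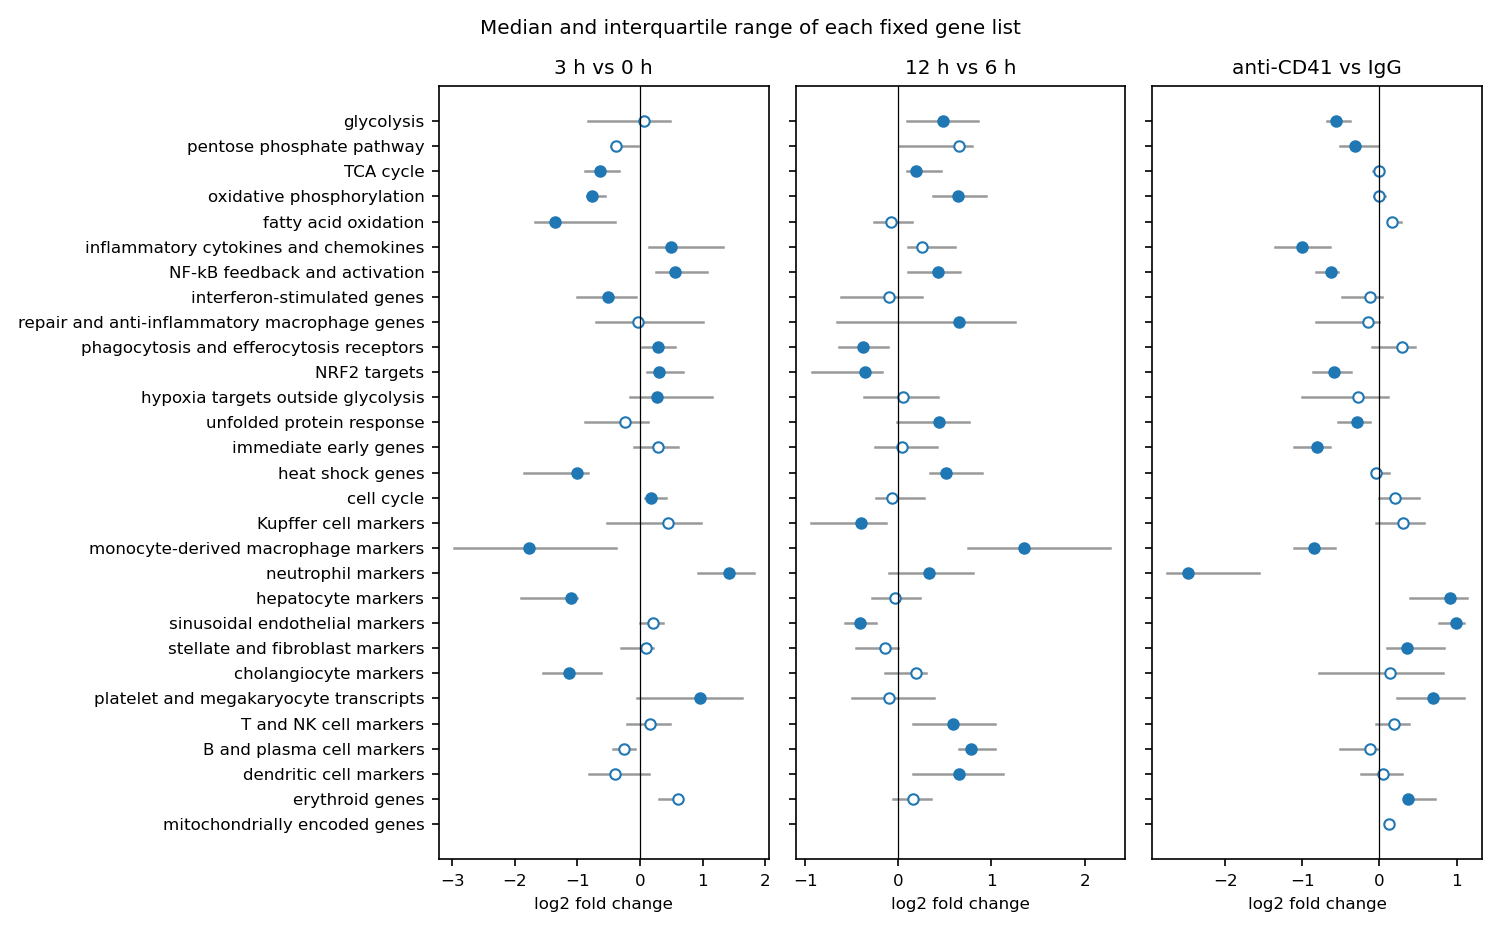
Median log2 fold change of each fixed gene list (points) with the interquartile range of its genes (bars), in 1 panel per comparison with its own horizontal scale; filled points have a camera adjusted p under 0.05 with the preset correlation. Oxidative phosphorylation lies at -0.76 for 3 h against 0 h, and neutrophil markers lie at -2.48 for anti-CD41 against IgG.

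The second comparison set 12 h against 6 h. No single gene was called. By camera with the preset correlation only, monocyte markers, glycolysis and oxidative phosphorylation ranked higher at 12 h and Kupffer cell markers lower. By fry the unadjusted p of these 4 lists was 0.281, 0.2, 0.284 and 0.0232. Gpnmb, a glycoprotein gene of lipid-laden and repair macrophages, was 6.05 ± 0.783 CPM at 6 h and 123 ± 93.0 CPM at 12 h (SD, n = 3 each). Clec4f was 3158 ± 330 and 1443 ± 390 CPM, and Aldoa was 544 ± 27.8 and 748 ± 167 CPM. None of the 3 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.697 for each). That test called 0 of 14010 genes, with 726 at an unadjusted p under 0.05 against 700 by chance, and the groups did not overlap in 9.28% of genes, against 10% by chance. DESeq2 called 3 genes, voom with library weights 0 and limma on FPKM 0. The split of these libraries into 6 h replicates 1 and 2 with 12 h replicate 1 against the others gave 15 calls. Without 12 h replicate 1, edgeR called 2 genes, 1 in each direction, with 3707 at an unadjusted p under 0.05.

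All lists called for 12 h against 6 h were called with the preset correlation only (adjusted p = 0.642 with an estimated correlation for each of the 16), and 0 members were called over all genes. Adjusted over the list alone, 1 repair gene was called higher and 2 NRF2 targets lower, and no member of the other lists. All 18 monocyte-derived macrophage markers had positive values (median 1.35; camera adjusted p = 9.3e-05), with S100a4 at 17.6 ± 23.0 and 205 ± 194 CPM. Their median was 3.17 without 6 h replicate 3 and 2.24 with voom. Kupffer cell markers had a median of -0.40, with 16 of 20 negative (camera adjusted p = 0.00143). The glycolysis median was 0.48, with 16 of 21 positive (camera adjusted p = 0.00164), and 0.38 without 12 h replicate 3 (camera adjusted p = 0.0781). Oxidative phosphorylation had a median of 0.64, with 27 of 28 positive (camera adjusted p = 2.1e-05), 0.96 without 12 h replicate 1 and 0.16 (camera adjusted p = 0.0304) without 12 h replicate 2. Repair and anti-inflammatory macrophage genes had a median of 0.65 (camera adjusted p = 0.00881), and 0.48 (camera adjusted p = 0.0639) without 12 h replicate 3. Sinusoidal endothelial markers had a median of -0.41 (camera adjusted p = 0.00104), 0.08 (camera adjusted p = 0.965) without 12 h replicate 3 and -1.19 without 12 h replicate 1, and it was -1.21 with voom and -0.73 with FPKM. The 12 h libraries differed widely: their mean monocyte marker levels were 5.44, 8.21 and 8.65 log2 CPM in replicates 1, 2 and 3, against 5.12, 5.21 and 7.39 at 6 h, and their endothelial levels were 9.29, 8.23 and 6.49, against 8.76, 8.72 and 8.95. In mean log2(CPM + 1), glycolysis was 6.43, 7.02 and 7.20 and oxidative phosphorylation 5.57, 6.94 and 6.05 in these 12 h libraries. Both were lowest in replicate 1, as were monocyte markers. Whether the mix of cells accounts for their rank was not tested.

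Further lists ranked higher at 12 h, each by camera with the preset correlation. T and NK cell markers, all 19 positive, had a median of 0.58 (camera adjusted p = 5.6e-04), 0.35 without 6 h replicate 1 (0.194) and 0.25 without 12 h replicate 2. B cell markers, all 13 positive, had a median of 0.78 (0.00762), which was not called without 12 h replicate 2 (0.136) or 12 h replicate 3 (0.281) and was 1.19 without 12 h replicate 1. Dendritic cell markers had 0.66 (0.00607), not called without 6 h replicate 1 (0.119) and 1.07 without 12 h replicate 1. Heat shock genes had 0.51 (0.00164), 0.79 without 12 h replicate 1 and 0.22 without 12 h replicate 2. NF-kB genes had 0.42 (0.00881), not called without 6 h replicate 1 (0.186). Neutrophil markers had 0.33 (0.0199), not called without 6 h replicate 3 (0.126), with voom (0.122) or with FPKM (0.0573), 0.51 without 6 h replicate 2 and 0.55 without 12 h replicate 1. Unfolded protein response genes had 0.44 (0.0244), not called without 6 h replicate 1 (0.162), 6 h replicate 3 (0.068) or 12 h replicate 2 (median 0.27, 0.283) or with voom (0.127). The tricarboxylic acid cycle had 0.19 (0.0192), 0.38 without 12 h replicate 1 and 0.12 with voom, and was not called without 6 h replicate 3 (0.126), 12 h replicate 2 (median 0.07, 0.251) or 12 h replicate 3 (median 0.32, 0.0686). Lower were the phagocytosis receptors at -0.37 (0.00762; -0.57 without 12 h replicate 1 and -0.63 with voom) and NRF2 targets at -0.35 (0.00679; -0.54 without 6 h replicate 3), the latter not called without 12 h replicate 1 (0.143). Not called were the pentose phosphate pathway (0.65, 0.107), inflammatory cytokines (0.26, 0.0599), stellate markers (-0.15, 0.0782), interferon-stimulated genes (-0.10, 0.173), cholangiocyte markers (0.19, 0.347), hypoxia targets (0.06, 0.632), immediate early genes (0.04, 0.632), fatty acid oxidation (-0.08, 0.632), hepatocyte markers (-0.04, 0.894) and erythroid genes (0.16, 0.947). Nor were cell cycle genes (median -0.07, mean 0.02, test direction up; 0.916) or platelet transcripts (median -0.10, mean 0.03, test direction down; 0.886). Of 12 alternatives besides the estimated correlation, inflammatory cytokines were called higher in 6, stellate markers lower in 5 (medians from -0.82 to 0.23), and the pentose phosphate pathway higher and interferon-stimulated genes lower in 3 each. Immediate early genes (camera adjusted p = 0.0491) and cholangiocyte markers (0.0178) were called higher without 6 h replicate 2, and fatty acid oxidation (0.0346) lower without 12 h replicate 2.

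Set side by side in plain CPM, without a test because 0 h and 3 h stand in another table than 6 h and 12 h, Aldoa was 479 ± 34.5, 427 ± 17.3, 543 ± 43.5 and 752 ± 174 CPM at 0, 3, 6 and 12 h (SD, n = 3 each). Pfkfb3 was 91.9 ± 0.932, 261 ± 91.7, 125 ± 42.2 and 85.6 ± 22.5 CPM. Ldha was 433 ± 43.8, 241 ± 33.3, 288 ± 15.2 and 455 ± 190 CPM. The levels of Il6 were 37.5 ± 15.1, 193 ± 83.1, 54.1 ± 39.7 and 18.5 ± 6.2 CPM. Clec4f was 1615 ± 444, 2197 ± 346, 3137 ± 226 and 1444 ± 368 CPM.

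**Figure D2:**
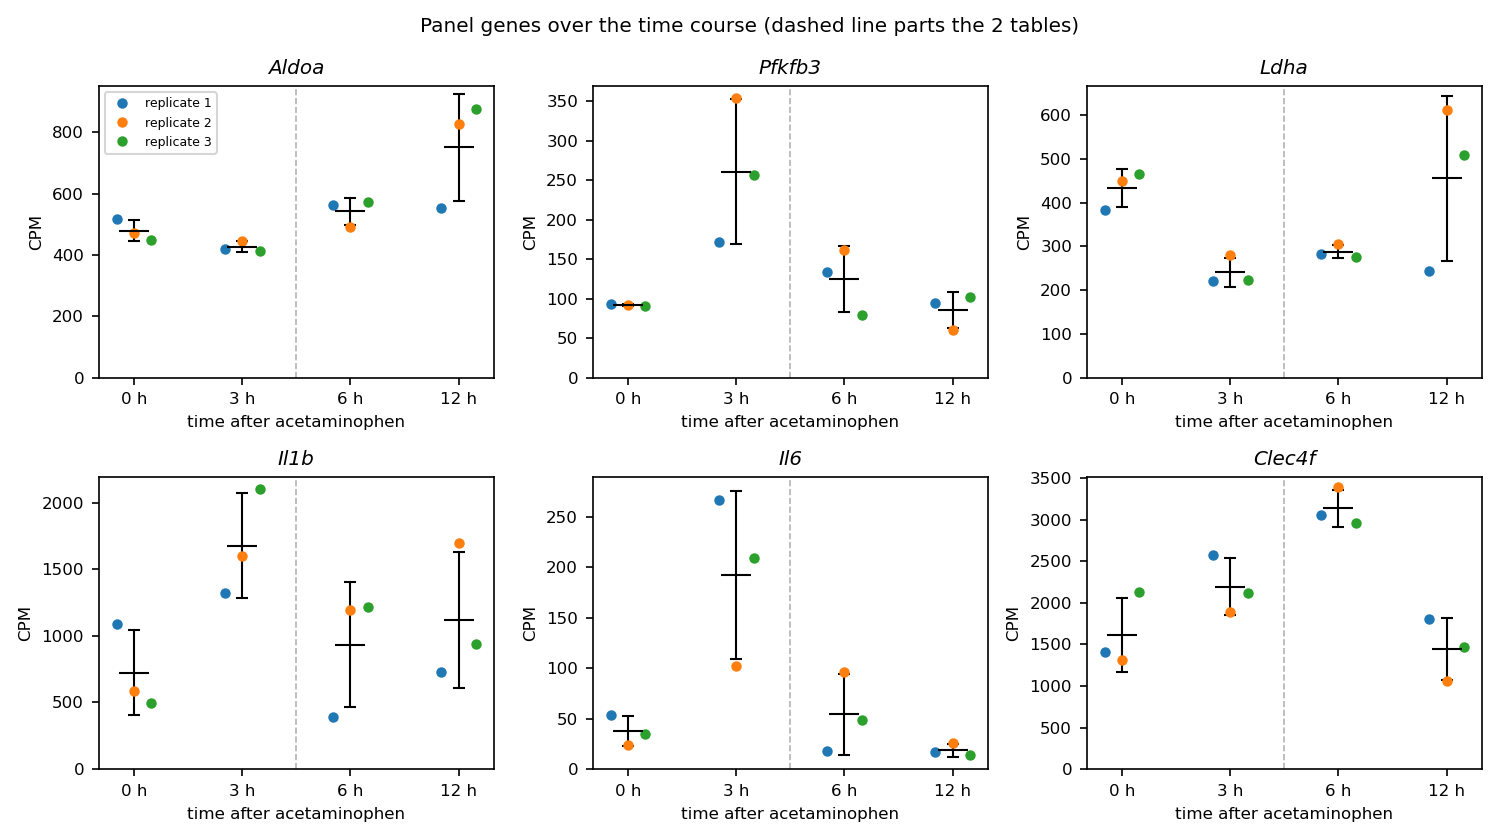
Levels of Aldoa, Pfkfb3, Ldha, Il1b, Il6 and Clec4f in plain CPM against hours after acetaminophen; points are libraries, bars the mean ± SD of 3 libraries, and the dashed line parts the separately made tables. Pfkfb3 and Il6 have their highest means at 3 h, 261 and 193 CPM, and Aldoa at 12 h, 752 CPM.

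The third comparison asked how Kupffer cells of acetaminophen-treated mice given anti-CD41 differed from those given IgG. Few genes were called. Sinusoidal endothelial markers ranked higher in the same comparison (median 0.99), by camera with the preset correlation only. Of the genes called, Plvap stands in that list and Bgn in the stellate list. Whether the called genes changed within Kupffer cells or through the mix of cells was not tested. Cyp26b1 (ENSMUSG00000063415; GRCm38 chromosome 6, 84571414 to 84593908), which encodes a retinoic acid hydroxylase, rose from 37.0 ± 13.7 to 240 ± 24.8 CPM (SD, n = 3 each). The chemokine-scavenging receptor gene Ackr4 rose by 3.29 on the log2 scale, the clock-controlled transcription factor gene Dbp by 2.25, the cadherin gene Cdh13 by 2.04, the endothelial gene Plvap by 1.48, Pcdh17 by 1.48 and the proteoglycan gene Bgn by 1.33. Gdf15 (ENSMUSG00000038508; GRCm38 chromosome 8, 70629393 to 70632456), a stress-induced cytokine gene, fell from 133 ± 15.9 to 45.9 ± 3.95 CPM. The other genes called were AU021092, Pla2r1 and Masp1, which were higher by 2.31, 1.47 and 1.37; they lie outside the naming rule and were chosen after their values were seen.

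With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 10 of 14905 genes were called higher and 1 lower with anti-CD41 (adjusted p from 0.0298 to 0.0441), all by at least 2-fold. At an unadjusted p under 0.05 there were 2757 genes against 745 by chance, and the groups did not overlap in 25% of genes, against 10% by chance. DESeq2 called 621 genes higher and 444 lower, and voom with library weights 447 and 232, in both cases with all 11 genes among them. With DESeq2 size factors within edgeR, 8 of the 11 were kept, and Ackr4 (edgeR adjusted p = 0.0513), Bgn (0.0571) and Pla2r1 were not called. With a library left out the calls changed more than the fold changes. None of the 11 was called without IgG replicate 1 (1 call), IgG replicate 2 (0), anti-CD41 replicate 2 (0) or anti-CD41 replicate 3 (0), with 2435, 2688, 1308 and 1435 genes at an unadjusted p under 0.05. In these fits the log2 change was 2.49 to 2.77 for Cyp26b1, 1.41 to 1.47 for Plvap and -1.60 to -1.49 for Gdf15, against 2.70, 1.48 and -1.53 with all libraries. Without IgG replicate 3 there were 3 calls (Gdf15, Plvap and Cyp26b1) and without anti-CD41 replicate 1 there were 110.

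Glycolysis genes ranked lower with anti-CD41. Of the 21 genes 20 had negative values, 0 were called over all genes and 10 were lower adjusted over the list alone (median -0.57; camera adjusted p = 9.7e-08, adjusted p = 0.548 with an estimated correlation). Aldoa (ENSMUSG00000030695) was 884 ± 60.0 CPM with IgG and 629 ± 96.7 CPM with anti-CD41 (SD, n = 3 each), a log2 difference of -0.49 ± 0.15 (SE) without overlap of the groups that was not called over all genes (edgeR unadjusted p = 0.0125, edgeR adjusted p = 0.183). The log2 values of Pkm, Ldha, Hk2 and Pfkfb3 were -0.62, -0.40, -0.38 and -0.57, and that of the glucose transporter gene Slc2a1 was -1.95, with an SD of 148 CPM around 166 CPM in the IgG libraries. Gapdh is uncertain in this table: it had 118 to 1200 counts per library, against 15574 to 48930 in the time-course tables, and the list median without it was -0.53 (camera adjusted p = 1.2e-07). The pentose phosphate list was lower (median -0.32; camera adjusted p = 0.0379, adjusted p = 0.67 with an estimated correlation; 3 of 7 adjusted over the list alone), but not without IgG replicate 1 (-0.13, camera adjusted p = 0.134), anti-CD41 replicate 2 (-0.23, camera adjusted p = 0.108) or anti-CD41 replicate 3 (-0.24, camera adjusted p = 0.08), and was at -0.52 without anti-CD41 replicate 1 and -0.49 with voom. The tricarboxylic acid cycle and oxidative phosphorylation lists had medians of -0.0005 and -0.01 and were not called (camera adjusted p = 0.518 and 0.994); the mean of the latter was 0.01. The 13 mitochondrially encoded genes, analysed here in this table only, had a median of 0.12 (camera adjusted p = 0.438).

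Activation genes also ranked lower with anti-CD41, again with 0 members called over all genes. Neutrophil and monocyte-derived macrophage markers were lower in the same comparison (medians -2.48 and -0.85). A change within Kupffer cells was therefore not separated from a change in the mix of cells. Of 23 immediate early genes all had negative values and 19 were lower adjusted over the list alone (median -0.82; camera adjusted p = 3.8e-11, adjusted p = 0.548 with an estimated correlation), with Egr2 at 53.2 ± 10.8 and 22.1 ± 3.41 CPM. All 19 genes of NF-kB feedback and activation had negative values and 13 were lower adjusted over the list alone (median -0.63; camera adjusted p = 1.4e-08, adjusted p = 0.548 with an estimated correlation); the median was -0.41 without IgG replicate 3. Of 19 inflammatory cytokine and chemokine genes 17 had negative values and 9 were lower adjusted over the list alone (median -1.01; camera adjusted p = 8.9e-08, adjusted p = 0.548 with an estimated correlation). Ccl2 was 121 ± 39.0 and 46.3 ± 9.67 CPM, and Il1b was 1137 ± 1019 and 253 ± 86.0 CPM. NRF2 targets (median -0.59; camera adjusted p = 4.6e-06; 10 of 17 lower adjusted over the list alone, adjusted p = 0.548 with an estimated correlation) included Srxn1 at 94.0 ± 18.0 and 53.2 ± 3.57 CPM. The unfolded protein response list was lower too (median -0.30; camera adjusted p = 7.3e-04; 1 of 16 adjusted over the list alone, adjusted p = 0.67 with an estimated correlation), with a median of -0.48 without anti-CD41 replicate 1.

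Markers of other cell types moved with the antibody groups. Endothelial markers were higher: 19 of 20 had positive values, Plvap was called over all genes and 16 were higher adjusted over the list alone (median 0.99; camera adjusted p = 4.0e-10, adjusted p = 0.562 with an estimated correlation), with Kdr at 679 ± 148 and 1575 ± 310 CPM. Neutrophil markers were lower, 14 of 20 adjusted over the list alone (median -2.48; camera adjusted p = 1.5e-06, adjusted p = 0.652 with an estimated correlation). IgG replicate 3 stood apart on them, at 6.10 log2 CPM against 4.06 and 3.82 in the other IgG libraries, and the median was -1.11 without it and -1.50 with voom. Monocyte-derived macrophage markers were lower, all 18 with negative values and 8 adjusted over the list alone (median -0.85; camera adjusted p = 2.6e-08, adjusted p = 0.548 with an estimated correlation), with Chil3 at 2226 ± 485 and 524 ± 265 CPM and a median of -0.56 without anti-CD41 replicate 2. Hepatocyte markers were higher, 7 adjusted over the list alone (median 0.91; camera adjusted p = 0.00446, adjusted p = 0.758 with an estimated correlation), though Hp was lower adjusted over the list alone, and the call was lost without anti-CD41 replicate 3 (0.65, camera adjusted p = 0.0882). Kupffer cell markers were not called (median 0.30; camera adjusted p = 0.3), except that they were higher without anti-CD41 replicate 1 (0.49, camera adjusted p = 0.00504), and their median ranged down to 0.12 over the alternatives.

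As a list, platelet and megakaryocyte transcripts were not lower with anti-CD41, though Pf4 had a lower mean level. Endothelial markers were higher in the same comparison, and which cells these transcripts came from was not tested. The list is therefore no measure of platelet depletion. Itga2b, which encodes CD41, was 3.81, 4.56 and 20.7 CPM in IgG replicates 1, 2 and 3 and 13.3, 20.3 and 20.8 CPM with anti-CD41, and was not called (edgeR adjusted p = 0.473). The list of 20 genes was higher, with 17 positive values and 2 genes higher adjusted over the list alone (median 0.70; camera adjusted p = 0.0113, adjusted p = 0.729 with an estimated correlation). Pf4 was 25 ± 9.32 and 15.9 ± 2.41 CPM and Alox12 was 13.6 ± 2.20 and 24.8 ± 2.58 CPM. The list call was lost without IgG replicate 1 (0.38, camera adjusted p = 0.122) or IgG replicate 2 (0.51, camera adjusted p = 0.0625), and the median was 1.198 without IgG replicate 3 and 1.11 with voom.

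Stellate markers were called higher with anti-CD41, with Bgn called over all genes and 3 of 17 over the list alone (median 0.36; camera adjusted p = 0.0288, adjusted p = 0.67 with an estimated correlation). This rested on single libraries: the median was 0.14 (camera adjusted p = 0.134) without IgG replicate 1, 0.06 (0.194) without IgG replicate 2, 0.86 without IgG replicate 3, 0.23 (0.0792) without anti-CD41 replicate 1, 0.10 without anti-CD41 replicate 3 and 0.75 with voom. Erythroid genes, all 6 positive and 0 called over all genes or the list alone, had a median of 0.36 (camera adjusted p = 0.0379, adjusted p = 0.67 with an estimated correlation). They were not called without IgG replicate 3 (0.137), anti-CD41 replicate 2 (0.0705) or anti-CD41 replicate 3 (median 0.24, 0.0882), with medians of 0.62 without IgG replicate 1 and 0.56 without anti-CD41 replicate 1, with DESeq2 and with no expression filter, and 0.55 with voom. Not called, with camera adjusted p in brackets, were fatty acid oxidation at 0.16 (0.128), interferon-stimulated genes at -0.13 (0.0527; 2 lower over the list alone), repair genes at -0.15 (0.0527; 1 lower over the list alone), phagocytosis receptors at 0.29 (0.224; 3 higher over the list alone), hypoxia targets at -0.28 (0.0617), cell cycle genes at 0.20 (0.0605; 2 higher over the list alone), cholangiocyte markers at 0.14 (0.778), T and NK cell markers at 0.19 (0.167), B cell markers at -0.12 (0.0527) and dendritic cell markers at 0.05 (0.688; 1 higher over the list alone). Heat shock genes had a median of -0.04 and a mean of 0.06 with test direction down (0.698). Some of these lists were called under other settings. Of 11 alternatives besides the estimated correlation, repair genes were called lower in 8, interferon-stimulated genes in 6 (medians from -0.31 to -0.06), hypoxia targets in 6 (medians from -0.43 to 0.02) and B cell markers in 4, and cell cycle genes were called higher in 4. Without IgG replicate 1, fatty acid oxidation (0.23, camera adjusted p = 0.0414) and T and NK cell markers (0.44, camera adjusted p = 0.0244) were called higher.

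**Figure D3:**
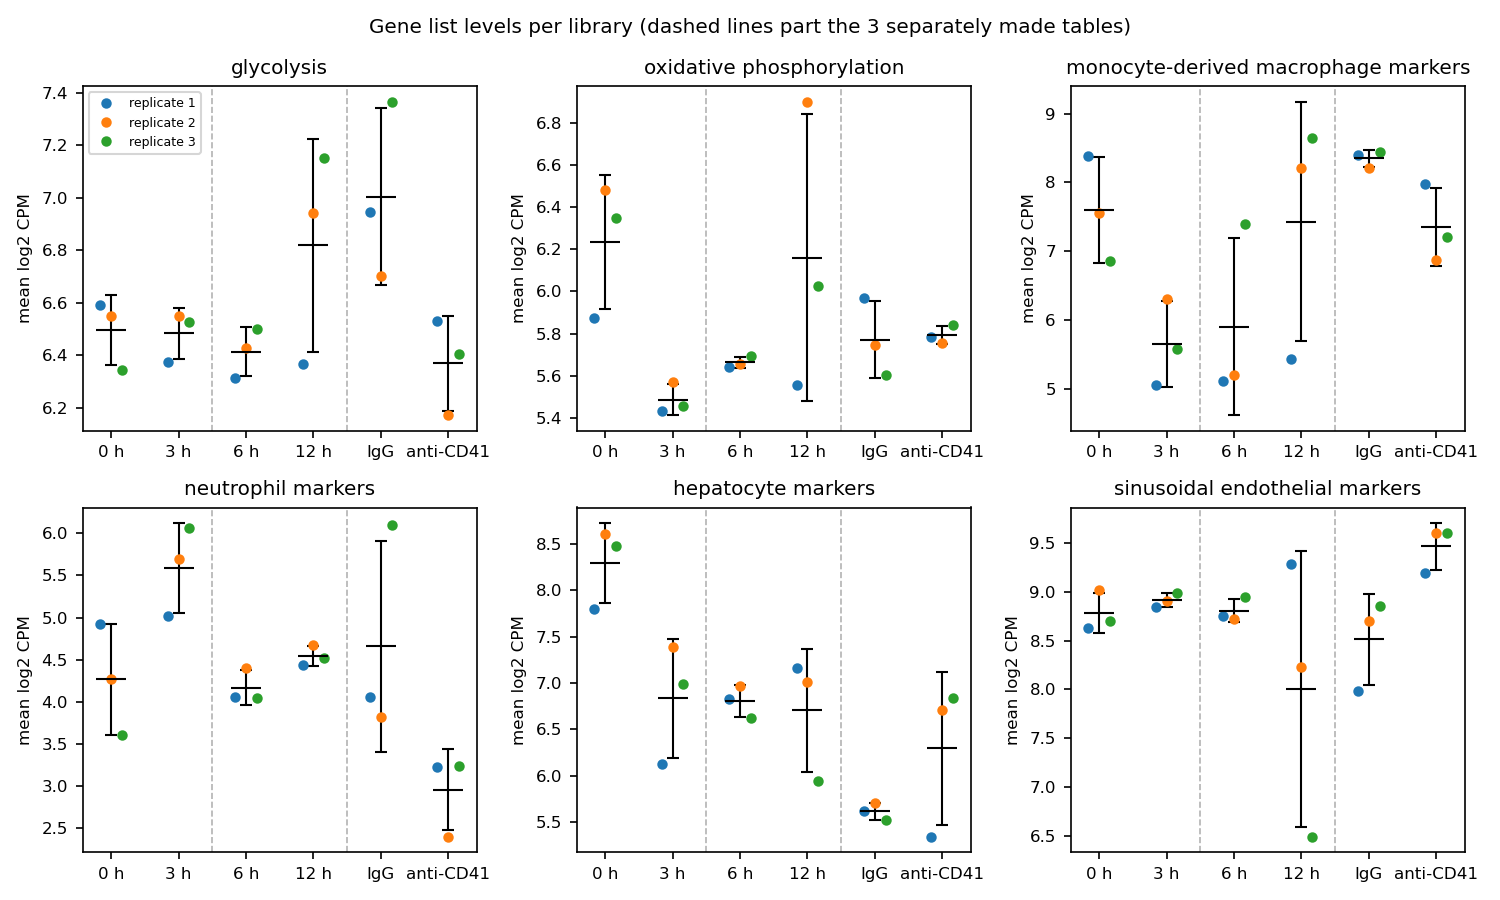
Mean log2 CPM of 6 gene lists in each of the 18 libraries (points), with the mean ± SD of each group of 3 (bars); dashed lines part the 3 separately normalised tables, between which levels were not tested. IgG replicate 3 stands apart on neutrophil markers at 6.10, and the 12 h libraries spread from 5.44 to 8.65 on monocyte markers.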

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

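Of the alternatives, voom with library weights and the glycolysis list without Gapdh were chosen after the data were seen, and the others were planned.

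For 3 h against 0 h, the 2703 genes called higher became 1783 with limma on FPKM and ranged from 1599 (without 0 h replicate 2) to 2671 (without 0 h replicate 1) over the libraries left out. The 3264 called lower ranged from 1855 (without 3 h replicate 3) to 3521 (without 0 h replicate 1). The median of the glycolysis list, which was not called, moved from 0.06 to 0.10 with voom and -0.0151 with FPKM, and from 0.00198 (without 0 h replicate 3) to 0.22 (without 0 h replicate 1). The causes were not tested.

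For 12 h against 6 h, DESeq2 called 2 genes higher and 1 lower in place of 0 by edgeR (726 at an unadjusted p under 0.05). Leaving out libraries gave 0 to 1 in each direction, 1 and 1 without 12 h replicate 1. The glycolysis median of 0.48 ranged from 0.38 (camera adjusted p = 0.0781, without 12 h replicate 3) to 0.67 (without 12 h replicate 1). Among lists that were not called, hepatocyte markers ranged over the libraries left out from -0.19 (without 12 h replicate 1) to 0.32 (camera adjusted p = 0.0137, without 12 h replicate 3) and erythroid genes from -0.61 (camera adjusted p = 0.00399, without 12 h replicate 2) to 0.51 (without 12 h replicate 1), so each was called in the direction opposite to its median without that library. With voom, hepatocyte markers were called lower at a median of -0.50. The causes were not tested.

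For anti-CD41 against IgG, the 10 genes higher and 1 lower became 621 and 444 with DESeq2 and 447 and 232 with voom, with all 11 kept in each. Leaving out libraries gave 0 to 91 higher and 0 to 19 lower, the most without anti-CD41 replicate 1. With 2 libraries left in a group, fewer samples carry the test. The glycolysis median of -0.57 ranged from -0.67 to -0.41 over the libraries left out and was -0.53 without Gapdh (camera adjusted p = 1.2e-07).

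With an estimated correlation camera called 0 lists in each comparison, in place of 16, 16 and 14. The medians are the same by construction, for glycolysis 0.48 (camera adjusted p = 0.642) at 12 h and -0.57 (0.548) with anti-CD41. The estimate was 0.895 for oxidative phosphorylation at 3 h, 0.694 for monocyte-derived macrophage markers at 12 h and 0.857 for endothelial markers with anti-CD41. The preset value was 0.01, which treats the genes of a list as nearly independent. For neutrophil markers at 12 h the estimate was 0.00454 and the call was lost as well. For platelet transcripts at 3 h it was -0.0556, and the unadjusted camera p still went from 0.00474 to 0.0388. A larger correlation thus does not account for every lost call. With an estimated correlation camera also takes its degrees of freedom from the samples, which are few, and not from the genes. A call lost in this setting therefore does not show that correlation between genes explains the list.

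The replicate block gave 295 genes higher and 89 lower with anti-CD41, with all 11 kept. It gave 15, 17 and 17 called lists in place of 16, 16 and 14, in the order of the comparisons, and NRF2 targets at 3 h were not called (camera adjusted p = 0.068). It also ended the 3 h calls of Taldo1 (edgeR adjusted p = 0.099), G6pdx (0.0958), Ccl2 (0.0613), Stab2 (0.0595) and Ccnb2 (0.0518). It was not used for calls: the labels do not say that a number pairs samples, and the deviations of same-numbered libraries did not correlate above 0.1 in every pair of any comparison (lowest r -0.126, -0.0464 and 0.0368). Libraries correlated best with their own number in the other group in 2, 3 and 5 of 6 cases. For the antibody groups, with 5 of 6 and a positive r in each pair, a structure shared by number stays open.

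Over named genes and alternatives, 4213 values kept their direction and side of the threshold, 118 lost a call, 148 gained a call and 27 changed sign without a call in either setting. Over lists, where the direction is that of camera's test and not of the median, the counts were 853, 115 and 56, and 51 changed the direction of the test without a call in either setting, besides the 2 reversals above. The FPKM settings for pseudocount, filter and quantile scaling were not run, because counts were the main data, nor was FPKM for the antibody groups, whose table holds none. In simulated data with few changed genes, 2-fold changes were found in 41.4% of cases at 3 h against 0 h. The share was 0% at 12 h against 6 h and 42.4% for anti-CD41 against IgG. The common biological coefficient of variation was 0.201, 0.371 and 0.267 in the same order. Depth was not varied apart from this spread, so what depth alone limits was not tested.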

Other observations

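Of the tests in this part, those on 12 h replicate 1 and those on the glycolysis list with anti-CD41 were chosen only after the result was seen.

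Glucocorticoid-induced genes rose at 3 h. Fkbp5, a chaperone gene of the glucocorticoid receptor pathway, rose from 57.7 ± 6.54 to 393 ± 117 CPM (SD, n = 3 each), the clock and glucocorticoid target gene Per1 from 96.6 ± 23.8 to 434 ± 92.9 CPM and the metallothionein gene Mt1 by 2.25 on the log2 scale. Of 12 genes 11 were called higher, over all genes and adjusted over the list alone, and Errfi1 fell by 1.31. The theme was chosen because Rasd1, Klf9 and Zbtb16, known targets of this receptor, had been seen among the genes with the smallest p at 3 h. They were left out of the list, which was fixed before the values of its single members were read, while Dusp1 and Ddit4 also stand in the immediate early and hypoxia lists. The hypothesis of a systemic glucocorticoid response passed its bound on this list: the median was 1.70 (camera unadjusted p = 1.2e-05, and 0.014 with an estimated correlation). Other inducers of these genes may act at the same time and were not tested.

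Clock genes were examined because Dbp was called with anti-CD41. Beside it, the clock repressor genes Nr1d1 (79.9 ± 26.2 and 148 ± 27.5 CPM) and Nr1d2 (63.5 ± 12.6 and 102 ± 19.2 CPM) had higher levels with anti-CD41, without overlap and without a call over all genes, and Nfil3, of the opposite phase, had 98.1 ± 35.6 and 42.2 ± 16.9 CPM. A different clock time of harvest may explain this: the median of 7 genes of the Dbp phase minus that of 4 genes of the opposite phase was 0.88 (camera unadjusted p = 0.308 and 0.0256 for the 2 lists, and 0.378 and 0.208 with an estimated correlation). By edgeR, 0 members of either list were called over all genes, and 2 of the first were higher and 2 of the second lower adjusted over the list alone. Ciart and Usp2, of the Dbp phase, had negative values (-0.34 and -0.43). More endothelial cells with anti-CD41 remain open, since the median of the 4 opposite-phase genes was -0.34 with an SD of 0.51 over these genes. That bound, written before the result was seen, was -0.3, and the value passes it by less than this spread. Nfil3 (-1.22) and Arntl (-0.49) lay below the bound, and Cry1 (-0.19) and Clock (-0.09) did not. Genes of the same libraries are not replicates. The labels give no harvest times.

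The library 12 h replicate 1 lay nearer to the 6 h libraries (mean r = 0.976) than to the other 12 h libraries (0.912); 12 h replicate 3 did so by less (0.932 and 0.93), and IgG replicate 2 lay nearer to the anti-CD41 (0.968) than to the other IgG libraries (0.966). An exchange with 6 h replicate 3 stays open: this library correlated better with the other 6 h libraries than with 12 h replicates 2 and 3 (difference -0.0285), but with the latter as well (0.941) as they did with each other (0.938), and its monocyte marker level of 7.39 log2 CPM lay nearer to theirs (8.21 and 8.65) than to 5.12 and 5.21 in the other 6 h libraries. A single wrong label or a swap with an outside sample was not excluded, and the tables argue against lower depth, with a total count of 0.96 times the mean of the other 12 h libraries. A smaller share of monocyte-derived cells may account for it: its marker level minus the lower of the other 12 h libraries was -2.77 log2 units. A biological difference between animals in the course of injury was not tested.

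The lower glycolysis list with anti-CD41 was weighed against the mix of cells. A uniform dilution of macrophages by endothelial cells is argued against by 12 pan-macrophage genes, with a median of 0.0473 (SD 0.323). They ran from -0.56 (Lyz2) to 0.50 (C1qc), with 7 of 12 positive. Csf1r was 2843 ± 431 and 2905 ± 246 CPM, but 2347 CPM in IgG replicate 3 against 3055 and 3127 CPM in IgG replicates 1 and 2. A median over genes that moved both ways cannot exclude dilution beside other shifts among macrophages. Depth is argued against by a ratio of mean total counts of 1.07. Fewer monocytes and neutrophils with anti-CD41 may contribute and stay open, since the higher of their list medians was -0.85. A change within Kupffer cells, which the antibody design would allow, cannot be separated from a change in the mix of cells by these values.

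Across 5581 genes called at 3 h, the anti-CD41 effect and the 3 h effect had a Pearson r of -0.31, with opposite signs in 52.2% of genes. This met the bound for the hypothesis that platelet depletion opposes the early change. It is left open nonetheless, because 6 of 10 splits of the antibody libraries gave an r as large in size, up to 0.45.

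Other splits of the 6 libraries of each comparison are too few, at 10, for a share under 0.05. As many genes were called in 1 of 10 splits at 3 h against 0 h (5967, highest other 0). For anti-CD41 against IgG it was 1 of 10 as well (11, highest other 1). At 12 h against 6 h the real grouping called 0 genes, so 10 of 10 splits reached it by construction and the count decides nothing (highest other 15). The split with 15 sets 6 h replicates 1 and 2 with 12 h replicate 1 against the others, as an exchange of 6 h replicate 3 with 12 h replicate 1 would, which points to a structure of the samples.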
